A study of Rattus norvegicus with 4 samples.

How the data were processed

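Single-cell RNA libraries of mucosal cells from the distal colon of rats were compared, 2 from normal rats and 2 from rats of the IBS-D model. Per the labels' protocols, tissue was digested, passed through a 40 µm strainer and sorted by flow cytometry, with no gate stated. The series' design text names the sigmoid colon. The sex of the rats is not given. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with cellranger 7.1.0, per the file headers. The submitters' processing notes name mRatBN7.2, Seurat 4.0.1, ArchR 1.0.2 and R 4.4.1. The lowest total of a barcode lay just above 500 UMIs, so empty droplets had been removed. The files list 30562 features, of which 544 share a symbol with another and are kept apart by symbol and ID, and 4367 have no symbol. None of these 4367 IDs matched the reference table, whose assembly is GRCr8, so 0 of them were named and no coordinates are given. Counts of genes with near-identical copies, such as the RT1 family, Rpl17, Ighg1, Rps4y2, Naip6 and Clec2d2, are uncertain, because reads may be split between copies.

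Cells with at least 300 genes, at least 500 UMIs and at most 25% mitochondrial UMIs were kept, which removed 833 barcodes for few genes and 515 for mitochondrial share of 35304. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold marked 2.04%, 3.47%, 0.0109% and 2.54% of the barcodes and was not used. Instead the expected number, 0.8% per 1000 barcodes, with the highest scores was removed in each library (438, 575, 661 and 723). Some of these also lay over the mitochondrial limit and are counted in both. Doublets within a class stay in. Free RNA was not subtracted, since only filtered barcodes are given, and markers of B cells, the epithelium or fibroblasts are given beside some of the lists that they can move. In all 31706 cells with 234451473 UMIs were kept. Counts were scaled to 10000 per cell and logged. Then 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 34 clusters. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, with seed 1.

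Clusters were named from 23 fixed marker classes. A name needed a marker score of at least 1 and at least 3 detected markers, each with a UMI in at least 10% of the cluster's cells and at 2 times the median share over clusters or more. A cycling score of at least 1.5 set cycling clusters of germinal centre B cell-like cells apart. It was not applied to other classes, so the plasma cell-like cluster, with a score of 1.546, was not called cycling. The rule on detection and these thresholds were set after the data were seen, because a first rule left B cell clusters unnamed. Under them 7 clusters with 1611 cells stayed unnamed. Classes are called "-like", since they rest on markers alone. Leading genes were those with the largest fold in clusters among genes in at least 20% of the cells, with 20 CPM added. Immune or stress genes led some named clusters: Ccl3, Ccl4 and Nr4a1 led B cell-like cluster 9, Il10 and Nr4a3 cluster 15, and Cxcl2 macrophage or monocyte-like cluster 18.

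UMIs were summed per library and class and tested in classes with at least 20 cells in every library, in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F test) and Benjamini-Hochberg adjustment within a class at 0.05. The 4 classes with the most cells are the main comparisons, and sums over all cells were tested the same way. The sums of B cell-like cells ran from 12698038 to 19428172 UMIs per library. Shares of cells were tested with edgeR on cell numbers and with a two-sided exact permutation test. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 (correlation 0.01, prior count 2), again with an estimated correlation, and with fry. These were 22 lists and 3 pattern lists. The first were junction barrier, mucus, antimicrobial defence, MHC class II and class I presentation, interferon response, inflammatory cytokines and NF-kB, pattern recognition, T cell activation, Th17 and regulatory T, plasma cell and IgA. Further ones were mast cell mediators, serotonin, ion and water transport, bile acid handling, fatty acid oxidation, unfolded protein response, cell cycle, Wnt and stem, extracellular matrix, dissociation and heat shock, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins and mitochondrially encoded genes. The model's effect in B cell-like and T cell-like cells was compared by an interaction term with the library as a block.

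The tests, the marker classes, the lists and the rule for named genes were fixed before the data were examined. By that rule, genes with a symbol, no immunoglobulin or T cell receptor segment and not mitochondrially encoded are named where they pass the adjusted threshold, have a mean of at least 20 CPM and have both libraries of one group above both of the other. Up to 10 per direction are named in the main classes and 3 in others. Where fewer than 5 pass, the 5 with the smallest p in each direction are given as not passing. Genes outside it (Hpgds, Gpc4, Sh3rf3, Aox3, Dppa3, Rps4y2, Ighg1 and IDs without a symbol) are named because few genes were called, a choice made after their values were seen, as was that of list members that pass over the list alone or not at all. Some members of the fixed lists are not reported here.

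Alternatives were DESeq2 1.42.0, its size factors in edgeR, no count filter or at least 50 counts in 2 libraries, each library left out and a mitochondrial limit of 10% or none. Others were no doublets removed, resolutions 0.5 and 1.5, clustering after ComBat, cells thinned to 2000 UMIs, other denominators of shares, and clusters 5 and 7 alone.

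The tests were run first on simulated data with known answers, with 50 genes changed per fold and comparison. Of genes changed 2-fold, edgeR called 58% in B cell-like, 54% in T cell-like, 14% in absorptive colonocyte-like and 42% in germinal centre B cell-like cells and 0% over all cells. Of those changed 8-fold it called 80.0%, 90.0%, 84%, 98% and 64%. Of unchanged genes 16, 12, 7, 20 and 4 were called. In B cell-like cells the 16 stood beside 6, 29, 39 and 40 calls of genes changed 1.5-, 2-, 4- and 8-fold. In each comparison the false share of the calls exceeded the threshold of 0.05. A cell cycle list raised by 0.5 on the log2 scale was called by camera with its preset correlation in each of these 5 comparisons and with an estimated correlation in none (adjusted p from 0.470 to 0.939), and 1 other list was called, in germinal centre B cell-like cells. Genes were drawn independently of each other. The simulation therefore cannot show how often the preset correlation gives false calls for lists whose genes vary together.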

Results

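Single-cell RNA sequencing was carried out on flow-sorted mucosal cells of the rat colon. There were 2 libraries from normal rats (replicates 1 and 3) and 2 from rats of a model of diarrhoea-predominant irritable bowel syndrome (IBS-D, replicates 1 and 2). In this model, pups are parted from their mothers for 180 minutes a day from postnatal day 2 to 14. They receive dilute acetic acid in the rectum from day 15 to 27 with 1 hour of restraint, and then rest for 2 weeks. According to its title, the series asks how the immune barrier of the mucosa is regulated in this condition. The libraries held 7604, 8802, 9212 and 9686 barcodes in the order normal 1, normal 3, IBS-D 1 and IBS-D 2. Their unique molecular identifiers (UMIs) numbered 63139558, 66453872, 66829061 and 69679079, with medians of 6293, 6003.5, 5342 and 5618.5 per barcode. After filtering, 6896, 7764, 8345 and 8701 cells were kept. The labels do not say whether the libraries came from separate animals, so the p-values below measure only the spread between these libraries, which may be technical. Expression is given as CPM, the UMIs of a gene scaled to the total of the UMIs summed per library and cell class, as mean ± SD (n = 2 libraries per group) from normal to IBS-D. Changes are log2 ratios of IBS-D to normal with their standard error (SE).

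The sorted cells were mostly lymphocytes. B cell-like cells, marked by Ms4a1 and Cd79a, held 41.6 ± 5.76% to 36.8 ± 2.73% of the cells (from normal to IBS-D, SD, n = 2) and T cell-like cells 20.01 ± 4.98% to 16.1 ± 3.16%. The share was 14.2 ± 5.32% to 11.7 ± 7.89% for absorptive colonocyte-like cells and 6.02 ± 1.31% to 11.7 ± 6.01% for germinal centre B cell-like cells, marked by Bcl6 and S1pr2. The share of cycling germinal centre B cell-like cells was 5.71% and 2.67% in the normal libraries and 11.7% and 3.30% in the IBS-D libraries. Goblet-like cells, which make the mucus of the colon, held 1.33 ± 0.0827% to 0.601 ± 0.206% (log2 change -1.15, SE 0.63, adjusted p = 0.697 in edgeR). Macrophage or monocyte-like cells held 1.27 ± 0.435% to 2.14 ± 0.584%. Fibroblast-like cells held 4.79 ± 0.343% to 6.202 ± 3.87%, plasma cell-like cells 0.696 ± 0.000380% to 0.445 ± 0.0366%, natural killer or cytotoxic innate lymphoid-like cells 0.343 ± 0.0480% to 0.554 ± 0.191%. The rarer classes were mast cell-like cells 0.168 ± 0.111% to 0.308 ± 0.175%, tuft-like cells 0.428 ± 0.215% to 0.419 ± 0.203%, enteric glia-like cells 0.144 ± 0.186% to 0.0415 ± 0.0261% and mesothelial-like cells 0.0346 ± 0.0125% to 0.0637 ± 0.0562%. Cluster 29, in which only the eosinophil markers Ccr3 and Siglec5 were detected, stayed unnamed. It held 6, 7, 39 and 54 cells, or 0.0886 ± 0.00223% to 0.544 ± 0.108% (log2 change 2.60, SE 0.70, adjusted p = 0.0992). The 7 unnamed clusters together held 5.93%, 3.63%, 5.73% and 5.08% of the cells of the 4 libraries.

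Of the 21 shares compared (14 named classes and 7 unnamed clusters), edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, and 1, that of cluster 29, had an unadjusted p under 0.05. With clusters at resolution 1.5 the share of cluster 29 had the same log2 change and passed (adjusted p = 0.0482), and over the other alternatives its adjusted p ran from 0.0756 (no doublets removed) to 0.943 (without normal 3). A two-sided exact permutation test of 2 against 2 libraries cannot give a p below 0.3333, the value of the goblet, macrophage and germinal centre B cell shares. Without IBS-D 1 the log2 change of the germinal centre B cell-like share was 0.32 against 0.96 with all libraries. The gate of the sort is not stated and can set these shares. When 1 goblet share was changed 8-fold in simulated data, it was called in 56% of 100 simulations.

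**Figure D1:**
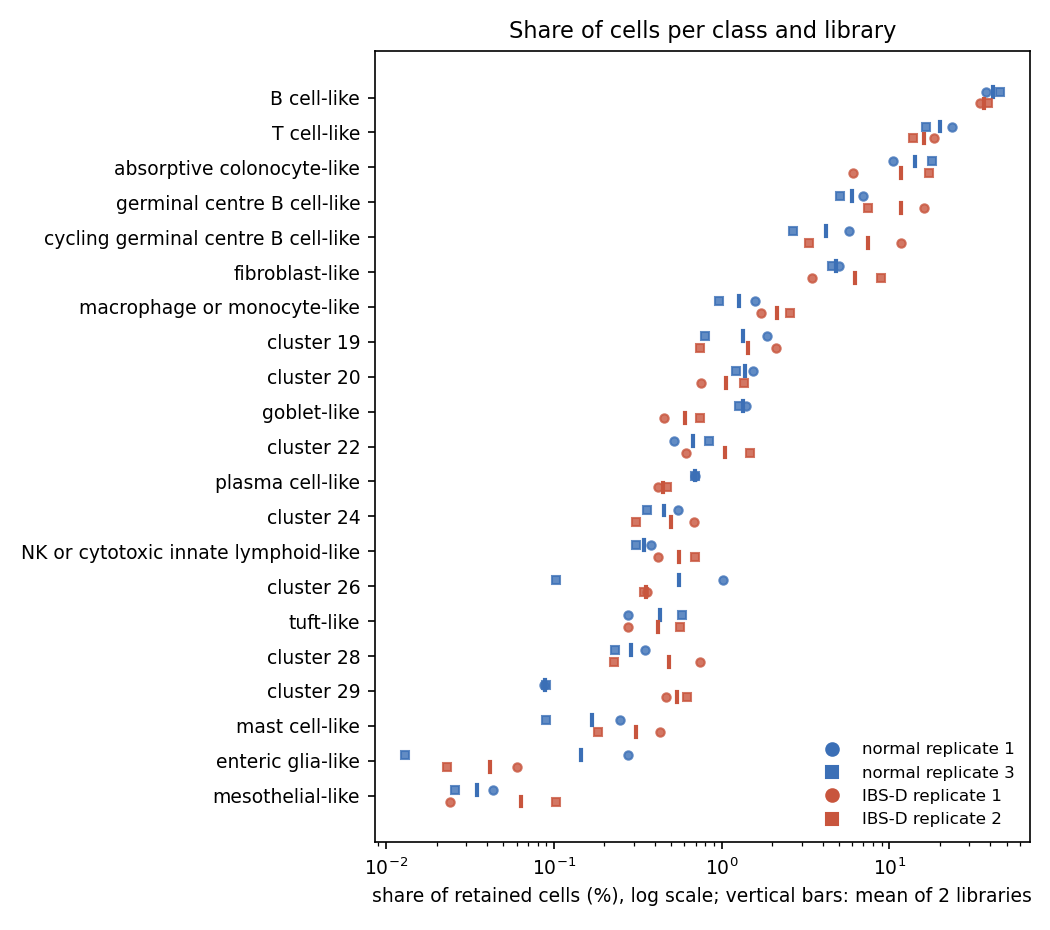
Share of retained cells (%, log scale) of each cell class or unnamed cluster in each of the 4 libraries, with normal libraries in blue, IBS-D libraries in red and a vertical bar at the mean of 2 libraries. The goblet-like share lies at 1.39% and 1.28% in the normal and 0.455% and 0.747% in the IBS-D libraries, and that of cluster 29 at 0.0870% and 0.0902% against 0.467% and 0.621%.

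In absorptive colonocyte-like cells, which take up salt and water and form most of the colonic surface, 5 genes with a symbol changed. Padi4 (ENSRNOG00000006855), an enzyme that turns arginine into citrulline in proteins, rose from 12.7 ± 2.02 to 68.5 ± 7.25 CPM (log2 change 2.31, SE 0.21, edgeR adjusted p = 0.0275). The heparan sulfate proteoglycan Gpc4 (ENSRNOG00000002413) rose from 2.85 ± 0.528 to 27.5 ± 1.36 CPM (log2 3.16, SE 0.28, adjusted p = 0.0275). Per2 (ENSRNOG00000020254), a repressor at the core of the circadian clock, fell from 120.5 ± 7.09 to 32.9 ± 0.685 CPM (log2 -1.98, SE 0.20, adjusted p = 0.0484). Ciart (ENSRNOG00000042717), another clock repressor, fell from 58.1 ± 13.4 to 1.99 ± 1.17 CPM (log2 -5.21, SE 0.44, adjusted p = 0.0275). Nrg4 (ENSRNOG00000015149), a growth factor of the epidermal growth factor family, fell from 58.6 ± 3.39 to 10.5 ± 0.0879 CPM (log2 -2.59, SE 0.21, adjusted p = 0.0243). For each of these 5 genes both IBS-D libraries lay on the same side of both normal libraries. The naming rule required this of all but Gpc4.

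Other genes of these cells did not pass the threshold and are given as values. Duoxa2, the maturation factor of the hydrogen peroxide-producing oxidase Duox2, stood at 23.0 ± 1.36 to 141 ± 34.3 CPM (log2 2.51, SE 0.26, adjusted p = 0.0526). Gpx2, an epithelial glutathione peroxidase, stood at 93.4 ± 0.891 to 440.0 ± 102 CPM (adjusted p = 0.101). Bok, of the Bcl-2 family, had means of 21.6 to 107 CPM, the beta-arrestin Arrb1 of 22.2 to 64.6 and Tmem125, a symbol that 2 features of the files share, of 9.70 to 40.9. Values in the other direction were those of the clock genes Dbp (142 to 10.2 CPM, adjusted p = 0.101) and Per3 (221 to 40.2, adjusted p = 0.0775). They were also those of the sterol 27-hydroxylase Cyp27a1 (53.8 to 13.5, adjusted p = 0.0742), the drug efflux pump Abcb1a (862 to 221, adjusted p = 0.101) and Mettl7b (120.2 to 34.5, adjusted p = 0.101). Duoxa2 passed without IBS-D 1 (adjusted p = 0.0139) and without IBS-D 2 (0.0485). Its log2 change was 1.66 in cluster 5 alone (adjusted p = 0.0844) and -0.41 in cluster 7 alone (adjusted p = 0.834), alternatives added after the data were seen.

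In absorptive colonocyte-like cells edgeR called 4 genes that rose and 3 that fell among 12275 tested, and 1067 had an unadjusted p under 0.05. Of those that rose, 2, ENSRNOG00000065796 and ENSRNOG00000037911, have no symbol. DESeq2 called 70 and 76. Different clusters held most of these cells in the 2 groups: cluster 5 held 20.1% and 28.3% of them in the normal and 67.5% and 85.9% in the IBS-D libraries, and cluster 7 the rest. Leaving out a library gave 1 (normal 1), 2 (normal 3), 14 (IBS-D 1) and 25 (IBS-D 2) changed genes. Without normal 1 and normal 3 in turn the adjusted p was 0.186 and 0.0610 for Padi4, 0.165 and 0.0538 for Gpc4. In the same order it was 0.100 and 0.0536 for Ciart, 0.100 and 0.0538 for Nrg4 and 0.0844 and 0.0538 for ENSRNOG00000037911. For Per2 it was 0.165 and 0.0610, and without IBS-D 1 and IBS-D 2 0.0937 and 0.0549. In the same removals of normal 1 and normal 3 the log2 change was 2.23 and 2.41 for Padi4, 3.05 and 3.28 for Gpc4, -1.97 and -2.00 for Per2, -4.84 and -5.48 for Ciart and -2.58 and -2.61 for Nrg4. It was -1.93 and -2.06 for Per2 without IBS-D 1 and IBS-D 2, and 6.86 and 6.07 for ENSRNOG00000037911 without normal 1 and normal 3. With a mitochondrial share of at most 10%, Padi4 (log2 1.76, adjusted p = 0.195), Gpc4 (log2 2.67, adjusted p = 0.214), Per2 (log2 -2.20, adjusted p = 0.129) and Nrg4 (log2 -2.10, adjusted p = 0.137) did not pass. With no doublets removed, Padi4 (log2 2.31, adjusted p = 0.0535), Gpc4 (log2 3.11, adjusted p = 0.0701) and Per2 (log2 -1.92, adjusted p = 0.0944) did not, nor did Per2 with at least 50 counts in 2 libraries (log2 -1.96, adjusted p = 0.0535). In cluster 5 alone, Padi4 (log2 1.64, adjusted p = 0.0814), Gpc4 (log2 2.32, adjusted p = 0.0595) and Nrg4 (log2 -2.48, adjusted p = 0.0530) did not pass. In cluster 7 alone none of the 5 genes passed (adjusted p from 0.0550 to 0.0864), with log2 changes of 2.28 for Padi4, 3.59 for Gpc4, -1.95 for Per2, -5.28 for Ciart and -2.17 for Nrg4.

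**Figure D2:**
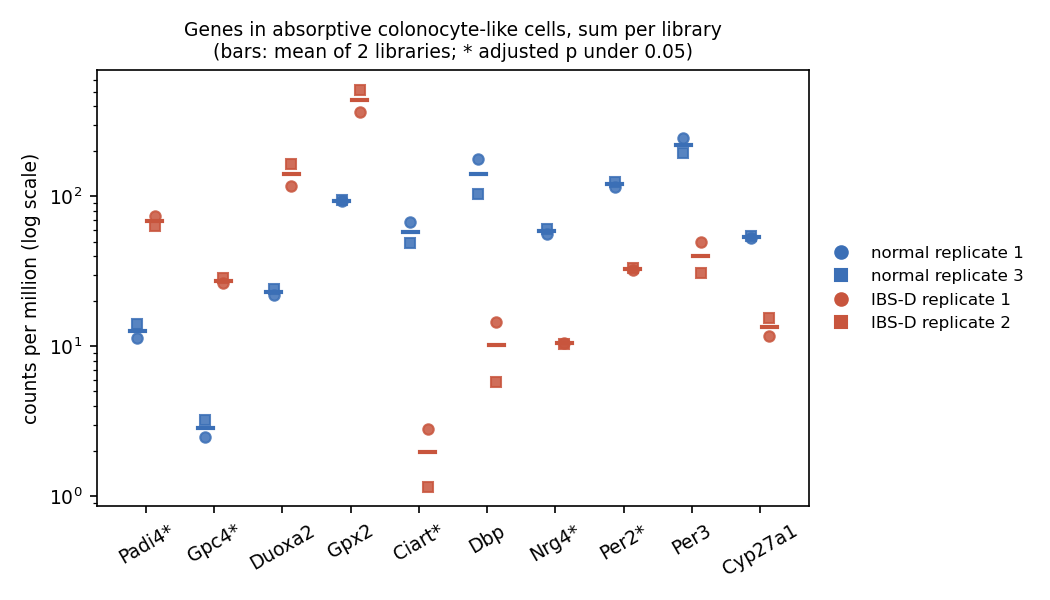
CPM (log scale) of 10 genes in absorptive colonocyte-like cells, summed per library, with normal libraries in blue, IBS-D libraries in red and a bar at the mean of 2 libraries. Genes with an asterisk passed an adjusted p of 0.05 in edgeR, among them Ciart at 67.5 and 48.6 CPM in the normal and 2.81 and 1.16 CPM in the IBS-D libraries.

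By gene list, inflammatory cytokine and NF-kB genes lay higher in absorptive colonocyte-like cells of IBS-D, 19 of 23 of them (median log2 0.84, camera adjusted p = 9.12e-05, adjusted p = 0.589 with an estimated correlation). Over all genes 0 of these passed, and adjusted over the list alone 4 rose: Nfkbia, the inhibitor of NF-kB (235 to 559.6 CPM), Nfkb1 (58.5 to 114), the cytokine Il10 (1.57 to 7.21) and the neutrophil chemokine Cxcl2 (1.90 to 7.70). Il10 and Cxcl2 were low here and are leading genes of B cell-like cluster 15 and macrophage or monocyte-like cluster 18. Whether their UMIs are free RNA of such cells was not tested. Nfkbia also differed between the clusters that hold the absorptive colonocyte-like cells. It stood at 544 and 354 CPM in the normal and 778 and 506 CPM in the IBS-D libraries in cluster 5, which held more of the IBS-D cells, and at 141 and 170.1 against 279 and 161 CPM in cluster 7. Within each cluster the libraries of the groups overlapped, and the lists were not tested within clusters. The list of MHC class II presentation had 13 of 14 genes higher (median 1.20, adjusted p = 0.000314, adjusted p = 0.606 with an estimated correlation). Of these 0 passed over all genes and 1 adjusted over the list alone, the costimulator Cd86 (10.1 to 23.0 CPM). The plasma cell and IgA list was higher too (12 of 14, adjusted p = 0.00561, adjusted p = 0.589 with an estimated correlation). So were those of T cell activation (7 of 7, 0.00135 and 0.589) and of the cell cycle (19 of 20, 0.00158 and 0.757). In the same cells the B cell marker Cd79a stood at 23.9 and 13.8 CPM in the normal and 83.7 and 22.6 CPM in the IBS-D libraries. The dissociation and heat shock list was also higher (18 of 22, median 0.49, adjusted p = 0.00135, adjusted p = 0.589 with an estimated correlation). The ribosomal protein list went the same way (58 of 72, 0.0482 and 0.840).

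Interferon response genes, which restrain viruses, lay lower in the absorptive colonocyte-like cells of IBS-D libraries (14 of 22, median log2 -0.39, adjusted p = 0.00792, adjusted p = 0.606 with an estimated correlation). Adjusted over the list alone 5 fell and over all genes 0 did, among them Ifit1 (8.46 to 0.912 CPM), Oasl2 (23.5 to 6.87) and Usp18 (7.23 to 0.610). The bile acid handling list had 7 of 8 genes lower (median -0.62, adjusted p = 0.0234, adjusted p = 0.606 with an estimated correlation). Adjusted over the list alone 4 fell and 1 rose (0 over all genes). The nuclear receptors Nr1i3 (25.02 to 9.46 CPM), Nr1h4 (62.0 to 34.0) and Vdr (155 to 99.3) and the bile acid exporter subunit Slc51b (18.1 to 2.98) were those that fell, and its partner Slc51a (5.60 to 14.9) the one that rose. The 13 mitochondrially encoded genes, a sign of RNA quality, were all lower (adjusted p = 0.00135, adjusted p = 0.606 with an estimated correlation). They made up 13.4% and 13.3% of the UMIs in the normal and 12.5% and 11.9% in the IBS-D libraries.

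The other 14 lists tested in absorptive colonocyte-like cells were not called. The junction barrier list had 12 of 19 genes higher (median log2 0.04, adjusted p = 0.239), with Tjp3, a protein of tight junctions, at 64.4 to 134 CPM. The antimicrobial defence list (adjusted p = 0.254) held 2 genes that rose adjusted over the list alone, Duoxa2 and the oxidase Duox2 (82.3 to 229 CPM), and 0 over all genes. The colonic ion and water transport list had 22 of 31 genes lower (median -0.19, adjusted p = 0.0682), with the sodium channel subunits Scnn1b at 29.8 to 12.6 CPM and Scnn1g at 23.1 to 4.93. The serotonin list (adjusted p = 0.0914) held the transporter Slc6a4, at 0.489 to 3.91 CPM, which rose adjusted over the list alone. The Wnt and stem list (adjusted p = 0.134) held Sox9 (14.3 to 34.9 CPM) and Ephb3 (2.58 to 10.2), which rose adjusted over the list alone. In the fatty acid list (adjusted p = 0.396) was the nuclear receptor Pparg (238 to 117 CPM), which fell in that sense. The adjusted p was 0.930 for mucus, 0.316 for MHC class I, 0.239 for pattern recognition and 0.668 for the Th17 and regulatory T list. In that list Il10 rose and Il1r1 (2.57 to 0.136 CPM) was among those that fell adjusted over the list alone. It was 0.788 for the unfolded protein response, 0.0647 for extracellular matrix, 0.941 for hypoxia and glycolysis and 0.788 for nuclear oxidative phosphorylation genes. For MHC class I the median was 0.01 while the mean was -0.11 and the test pointed lower. For the Th17 list the median was 0.01 and the mean -0.17 with the test lower. They were 0.00 and -0.14 for mucus and -0.01 and 0.02 for hypoxia and glycolysis, both with the test higher.

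Camera with its preset correlation called 10 of the 24 lists in absorptive colonocyte-like cells. With an estimated correlation it called 0, and fry called 0 (2 lists had an unadjusted p under 0.05). Without normal 3 the calls ended of the NF-kB list (adjusted p = 0.105), the interferon list (0.202), the plasma cell list (0.0880) and the ribosomal list (0.848, with the direction reversed). Without IBS-D 1 those ended of MHC class II (0.168), bile acid handling (0.127) and the cell cycle (0.832), and without IBS-D 2 that of the interferon list (0.549). Also without IBS-D 1, the ribosomal list was called in the other direction (0.00441).

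In B cell-like cells, the class with the most cells, 2 genes with a symbol fell. Med18 (ENSRNOG00000067073), a subunit of the Mediator complex that links transcription factors to RNA polymerase II, fell from 53.6 ± 3.60 to 13.7 ± 0.819 CPM (log2 -2.06, SE 0.13, edgeR adjusted p = 0.00175). Hpgds (ENSRNOG00000006583), the haematopoietic prostaglandin D synthase, fell from 18.5 ± 3.06 to 1.30 ± 0.0577 CPM (log2 -3.90, SE 0.23, adjusted p = 0.00175). ENSRNOG00000065796, which has no symbol in the files, rose from 1.13 ± 0.0782 to 101 ± 5.20 CPM (log2 6.38, SE 0.15), and ENSRNOG00000037911 from 23.7 ± 0.475 to 182 ± 5.94 CPM (log2 2.85, SE 0.11). Among the genes that did not pass, means were 30.6 to 63.2 CPM for Il1rapl1 (adjusted p = 0.396), 28.0 to 59.7 for Arhgap6 and 106 to 165 for the translation factor Eif2s3. They were 63.3 to 98.6 for the histone demethylase Kdm5c and 23.2 to 38.1 for the adhesion molecule Icam2. In the other direction they were 38.2 to 13.1 CPM for the stress-responsive sestrin Sesn2 (adjusted p = 0.396), 57.5 to 33.9 for Prkrip1, 3478 to 2247 for the ribosomal protein gene Rpl17, 85.0 to 51.9 for Pwp1 and 36.9 to 25.3 for Tmem64. In all, edgeR called 4 genes that rose and 2 that fell of 12649, with 582 at an unadjusted p under 0.05, and DESeq2 called 19 and 10. Without normal 1, IBS-D 1 and IBS-D 2 edgeR called 11, 16 and 48.

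Several lists shifted in B cell-like cells. The cell cycle list had 21 of 25 genes higher (median log2 0.38, camera adjusted p = 8.22e-05, adjusted p = 0.737 with an estimated correlation), with the thymidylate synthase Tyms at 0.805 to 2.60 CPM. The plasma cell and IgA list had 10 of 14 higher (median 0.23, adjusted p = 0.00215, adjusted p = 0.737 with an estimated correlation), with Prdm1, the regulator of plasma cell fate, at 6.95 to 12.4. The interferon response list had 15 of 23 lower (median -0.19, adjusted p = 0.00436, adjusted p = 0.737 with an estimated correlation), with Mx1, a GTPase that blocks influenza viruses, at 42.4 to 32.0 CPM and Rtp4 at 19.4 to 14.1. The 17 extracellular matrix genes were all higher (adjusted p = 0.00669, adjusted p = 0.825 with an estimated correlation). Of 12 mucus genes 10 were lower (adjusted p = 0.00873, adjusted p = 0.737 with an estimated correlation). Both lists hold genes of other cell types. The collagen gene Col1a1 stood at 25.02 to 39.7 CPM in B cell-like and at 17472 to 17602 CPM in fibroblast-like cells, whose share was 5.03% and 4.55% in the normal and 3.46% and 8.94% in the IBS-D libraries. The summed epithelial markers stood at 112 and 534 CPM in B cell-like cells of the normal and 127 and 382 CPM in those of the IBS-D libraries. Ribosomal protein genes (70 of 74 lower, adjusted p = 0.737 with an estimated correlation), nuclear oxidative phosphorylation genes (65 of 79, 0.825) and the 13 mitochondrially encoded genes (all lower, 0.737) were called too. The 18S ribosomal RNA gene Rn18s stood at 1493, 116, 52.4 and 513 CPM, apart between libraries and not between groups.

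Over all genes and adjusted over the list alone, 0 members of these lists passed in B cell-like cells. The list of mast cell mediators, of which Hpgds is a member, was not called (adjusted p = 0.620). Camera with its preset correlation called 8 of 23 lists, camera with an estimated correlation 0, and fry 0, with 2 at an unadjusted p under 0.05. Without normal 3 the calls ended of the cell cycle (adjusted p = 0.0858), plasma cell (0.0858), interferon (0.0858) and mucus (0.160) lists. Without IBS-D 1 those ended of the cell cycle (0.166), plasma cell (0.0563) and mucus (0.0797) lists, and without IBS-D 2 those of interferon (0.137) and extracellular matrix (0.208, reversed). Without normal 1 those ended of interferon (0.0501), extracellular matrix (0.189) and oxidative phosphorylation (0.302).

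In T cell-like cells, Med18 fell from 40.1 ± 3.39 to 11.6 ± 0.0582 CPM (log2 -1.89, SE 0.15, edgeR adjusted p = 0.0359). Sh3rf3 (ENSRNOG00000046791), a ubiquitin ligase with SH3 domains, fell from 11.6 ± 1.77 to 0.688 ± 0.117 CPM (log2 -4.13, SE 0.35, adjusted p = 0.0380). ENSRNOG00000065796 rose from 0.911 ± 0.430 to 81.6 ± 6.34 CPM and ENSRNOG00000037911 from 19.6 ± 0.538 to 146 ± 3.74 CPM. Among the genes that did not pass, means were 205 to 571 CPM for Abtb3 (adjusted p = 0.218), 57.7 to 109 for Plekha5 and 16.1 to 29.8 for Usp53. They were 29.2 to 48.1 for the clock repressor Cry2 and 32.1 to 55.6 for the lectin Clec2d2, one of a family of close copies. In the other direction they were 129 to 67.3 CPM for the channel gene Calhm6 (adjusted p = 0.282), 106 to 62.8 for Stox2, 53.7 to 36.7 for Arhgef10, 49.2 to 32.2 for Inafm1 and 118 to 72.4 for the dermatan sulfate epimerase Dse. These 4 called genes were all of 11407 tested, with 591 at an unadjusted p under 0.05, and DESeq2 called 8 that rose and 9 that fell. Without IBS-D 1 and IBS-D 2 edgeR called 7 and 64. Removal of normal 1 or normal 3 ended the calls of Med18 (log2 -1.89 and -1.89, adjusted p = 0.135 and 0.0803) and Sh3rf3 (log2 -4.20 and -4.07, adjusted p = 0.182 and 0.122). Sh3rf3 did not pass at a clustering resolution of 1.5 (log2 -4.07, adjusted p = 0.0504) or with cells thinned to 2000 UMIs (log2 -3.41, adjusted p = 0.201).

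The cell cycle list stood out in T cell-like cells, with 23 of 25 genes higher in IBS-D (median log2 1.34, camera adjusted p = 2.17e-14, adjusted p = 0.785 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 17 rose, such as the proliferation marker Mki67 (5.58 to 19.5 CPM), the ribonucleotide reductase subunit Rrm2 (2.77 to 9.75), Cenpf (3.39 to 12.5) and Ube2c (4.18 to 20.8). The class pools clusters 6, 8, 12 and 13, whose mix differed between libraries. In the order normal 1, normal 3, IBS-D 1 and IBS-D 2, cluster 8 held 393, 306, 634 and 320 cells. Cluster 13 held 146, 199, 387 and 147, of 1623, 1280, 1532 and 1208 T cell-like cells. The cell cycle list was not tested within clusters. All 14 genes of MHC class II presentation were higher (median 0.90, adjusted p = 0.000248, adjusted p = 0.785 with an estimated correlation), with 0 past either adjustment, among them RT1-Db1 (77.4 to 211 CPM) and the invariant chain Cd74 (76.4 to 184). The B cell marker Cd79a stood at 24.3 and 30.4 CPM in T cell-like cells of the normal and 64.3 and 20.5 CPM in those of the IBS-D libraries. Removal of IBS-D 1 ended the MHC class II call (adjusted p = 0.386). Ribosomal protein genes (70 of 73 lower, adjusted p = 0.785 with an estimated correlation) and the 13 mitochondrially encoded genes (all lower, 0.785) were called as well. Of 22 lists, camera called 4 with its preset correlation and 0 with an estimated one, and fry 0, with 0 at an unadjusted p under 0.05.

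In germinal centre B cell-like cells, which mutate and select antibody genes, Trio (ENSRNOG00000012148) rose from 2.75 ± 0.361 to 37.5 ± 3.32 CPM (log2 3.70, SE 0.25, edgeR adjusted p = 0.000218). The aldehyde oxidase Aox3 (ENSRNOG00000014555) fell from 12.5 ± 6.73 to 0.781 ± 0.0289 CPM (log2 -3.99, SE 0.49, adjusted p = 0.0239). ENSRNOG00000065796 and ENSRNOG00000037911 rose from 1.93 ± 0.7997 to 77.5 ± 6.86 and from 16.9 ± 2.39 to 166 ± 24.6 CPM. Among the genes that did not pass, means were 216 to 423 CPM for the histone demethylase Kdm6a (adjusted p = 0.277), 69.6 to 119 for the DNA primase subunit Prim1 and 19.6 to 38.6 for the E2F partner Tfdp2. They were 22.4 to 44.5 for Sapcd1 and 18.0 to 34.2 for the phospholipase Pla2g6. In the other direction they were 43.4 to 21.9 CPM for the kinesin-associated protein Kifap3 (adjusted p = 0.215), 45.8 to 24.0 for Aspn, 34.9 to 18.7 for the potassium channel Kcnn4, 63.02 to 33.4 for Kiaa0040 and 30.5 to 16.1 for Sesn2. EdgeR called 4 genes that rose and 1 that fell of 10669, with 462 at an unadjusted p under 0.05, and DESeq2 called 7 and 4. Without normal 1, normal 3, IBS-D 1 and IBS-D 2 edgeR called 9, 57, 37 and 94. With no doublets removed Trio had a log2 change of 1.82 and an adjusted p of 0.194.

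In germinal centre B cell-like cells, 24 of 25 cell cycle genes were higher (median log2 0.30, camera adjusted p = 1.40e-06, adjusted p = 0.726 with an estimated correlation). Of them 0 passed over all genes. Adjusted over the list alone 1 rose, the replicative helicase subunit Mcm6 (86.9 to 145 CPM). Cycling clusters were set apart from these cells by a score on genes of the cell cycle list, such as Mki67, a marker of this class too. The plasma cell and IgA list had 10 of 12 genes lower (median -0.31, adjusted p = 0.00314, adjusted p = 0.726 with an estimated correlation). In the cycling cells it had 11 of 13 lower (adjusted p = 0.00300, adjusted p = 0.908 with an estimated correlation), where Prdm1 fell adjusted over the list alone (46.4 to 20.1 CPM). The pattern recognition list had 13 of 19 lower (median -0.06, adjusted p = 0.0138, adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone 2 genes fell, the flagellin receptor Tlr5 (3.44 to 0.391 CPM) and Naip6 (6.72 to 1.52), a member of a family of near-identical copies. The 15 extracellular matrix genes were all higher (adjusted p = 0.821 with an estimated correlation). They include genes of fibroblasts, such as Col1a1 at 19.3 to 36.9 CPM, and the fibroblast-like share was 5.03% and 4.55% in the normal and 3.46% and 8.94% in the IBS-D libraries. Lower were 68 of 71 ribosomal protein genes (0.821), 60 of 78 oxidative phosphorylation genes (0.922) and all 13 mitochondrially encoded genes (0.821). Of 22 lists, camera called 7 with its preset correlation and 0 with an estimated one, and fry 0, with 1 at an unadjusted p under 0.05. Without normal 3 the calls ended of pattern recognition (adjusted p = 0.223) and the plasma cell list (0.0883). Without IBS-D 2 those ended of the plasma cell list (0.0692), extracellular matrix (0.920, reversed) and oxidative phosphorylation (0.664). Without normal 1 those ended of the plasma cell (0.106), extracellular matrix (0.264), oxidative phosphorylation (0.134, reversed), ribosomal (0.257) and mitochondrial (0.220) lists. In the cycling cells the adjusted p of the plasma cell list was, without normal 1 and IBS-D 2, 0.0892 and 0.0817.

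In cycling germinal centre B cell-like cells, Trio rose from 2.98 ± 1.79 to 38.8 ± 5.18 CPM (log2 3.75, SE 0.32, edgeR adjusted p = 0.00156). Dppa3, known from germ cells and early embryos, fell from 32.4 ± 4.95 to 5.06 ± 1.01 CPM (log2 -2.68, adjusted p = 0.00128). The immunoglobulin G constant gene Ighg1 fell from 53.3 ± 11.96 to 11.8 ± 2.44 CPM (log2 -2.23, adjusted p = 0.0201) and Rps4y2, a ribosomal protein gene with close copies, from 14.8 ± 0.359 to 3.86 ± 0.422 (log2 -1.98, adjusted p = 0.0369). EdgeR called 3 genes that rose and 3 that fell of 11184, with 509 at an unadjusted p under 0.05, and DESeq2 called 9 and 12. Removal of normal 1 ended the calls of Ighg1 (log2 -1.88, adjusted p = 0.0580) and Rps4y2 (-1.93 and 0.218), and removal of normal 3 that of Rps4y2 (-2.04 and 0.0519). The preset correlation gave calls for 7 of 22 lists (1 higher, 6 lower), among those lower 67 of 72 ribosomal protein genes (adjusted p = 2.13e-10), 71 of 79 nuclear oxidative phosphorylation genes (1.17e-06) and the 13 mitochondrially encoded genes (1.21e-07), each with adjusted p = 0.908 with an estimated correlation. The first of these calls ended without normal 1 (0.0706), the second without normal 1 (0.608) and IBS-D 2 (0.223). The 14 extracellular matrix genes were the list that lay higher (1.00e-05 and 0.908), not called without normal 1 (0.0892) or IBS-D 2 (0.0577). Unfolded protein response genes (17 of 19, 0.0161 and 0.908) and Wnt and stem genes (8 of 9, 0.0405 and 0.908) were lower too. Their calls ended without normal 3 (0.356 and 0.444), the first also without IBS-D 2 (0.364) and the second without IBS-D 1 (0.361). For all lists an estimated correlation and fry gave 0, with 0 of fry's at an unadjusted p under 0.05. Ighg1 did not pass at a resolution of 0.5 (log2 -1.18, adjusted p = 0.998) or 1.5 (-1.23 and 0.996), after ComBat (-1.44 and 0.9998), or with a mitochondrial limit of 10% or none (-1.25 and -1.13, 0.998 in both). Rps4y2 did not pass at a resolution of 0.5 (log2 -1.98, adjusted p = 0.0576), after ComBat (-1.62 and 0.275) or with no doublets removed (-1.69 and 0.360). With a mitochondrial limit of 10% or none its log2 change was -2.03 and -1.98 (adjusted p = 0.0514 and 0.0534). Without normal 3, IBS-D 1 and IBS-D 2 edgeR called 33, 20 and 67 genes.

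In fibroblast-like cells, Dbp (ENSRNOG00000021027), a transcription factor driven by the clock, fell from 145 ± 2.71 to 17.8 ± 1.31 CPM (log2 -3.10, SE 0.19, edgeR adjusted p = 0.00859). It was 1 of 2 changed genes of 11493, the other being ENSRNOG00000065796, with 463 genes at an unadjusted p under 0.05, and DESeq2 called 11 and 15. Interferon response genes lay lower, 21 of 22 of them (median log2 -0.70, camera adjusted p = 6.10e-13, adjusted p = 0.578 with an estimated correlation). Over all genes 0 passed and adjusted over the list alone 7 fell, among them Ifit3 (45.8 to 19.8 CPM), Ifit2 (47.1 to 22.2) and Oasl2 (40.4 to 17.8). The extracellular matrix list was lower (median -0.20, adjusted p = 0.0343, adjusted p = 0.754 with an estimated correlation), with the proteoglycan Dcn at 7713 to 5387 CPM. Lists that can follow RNA quality lay lower in the same cells: 67 of 71 ribosomal protein genes (median -0.26, adjusted p = 2.89e-09), 67 of 77 nuclear oxidative phosphorylation genes (-0.14 and 0.000215) and 12 of 13 mitochondrially encoded genes (-0.18 and 0.0324). Each had adjusted p = 0.754 with an estimated correlation. Ribosomal protein genes held 8.60% and 7.50% of the UMIs in the normal and 7.19% and 7.09% in the IBS-D libraries, and the call of their list was kept without each library in turn (adjusted p from 9.23e-10 to 0.0278), as was that of the interferon list (from 4.16e-10 to 1.10e-07). The oxidative phosphorylation call ended without IBS-D 1 (0.119), and the mitochondrial call without each library (from 0.0657 to 0.127). Mucus genes (9 of 10, 0.0257 and 0.754) were called lower, though not without normal 3 (0.257), and cell cycle genes (11 of 16, 0.000215 and 0.754) higher. Removal of IBS-D 1 or IBS-D 2 ended the call of Dbp (log2 -3.05 and -3.18, adjusted p = 0.108 and 0.0832), and removal of normal 1 or IBS-D 2 that of the matrix list (0.628 and 0.796). Of 22 lists, camera called 7 with its preset correlation and 0 with an estimated one, and fry 0, with 2 at an unadjusted p under 0.05. Without normal 1, normal 3 and IBS-D 1 there were 3, 4 and 1 changed genes.

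In macrophage or monocyte-like cells, the 11 tested genes of MHC class II presentation were all lower in IBS-D (median log2 -0.67, camera adjusted p = 8.55e-06, adjusted p = 0.652 with an estimated correlation). In this list 2 genes fell adjusted over the list alone, Cd74 (2345 to 1385 CPM) and RT1-Ba (827 to 479), and over all genes 0 did. The inflammatory cytokine and NF-kB list had 18 of 22 genes lower (median -0.14, adjusted p = 0.0238, adjusted p = 0.652 with an estimated correlation), with the prostaglandin synthase Ptgs2 at 279 to 73.8 CPM and the macrophage growth factor Csf1 at 33.1 to 9.62. All 7 lists called in these cells lay lower, among them 65 of 67 ribosomal protein genes (median -0.31, adjusted p = 3.90e-11, adjusted p = 0.806 with an estimated correlation) and the 13 mitochondrially encoded genes (median -0.32, 0.000531 and 0.652). Both of these calls were kept without each library in turn (up to 0.00162 and 0.0411). The others were 61 of 75 nuclear oxidative phosphorylation genes (0.0107 and 0.970), 9 of 10 extracellular matrix genes (0.0345 and 0.930) and 5 of 5 mucus genes (0.00381 and 0.930). The oxidative phosphorylation call ended without normal 1 (0.478) and IBS-D 2 (0.484, reversed). Without normal 3 and IBS-D 1 the calls ended of extracellular matrix (0.735, reversed, and 0.775) and mucus (0.301 and 0.430). Of the 109, 75, 144 and 222 cells of this class in normal 1, normal 3, IBS-D 1 and IBS-D 2, cluster 18 held 68, 57, 102 and 219, and clusters 31 and 32 the rest. The median UMIs per macrophage or monocyte-like cell were 9129 and 9013 in the normal and 5132 and 5778 in the IBS-D libraries. EdgeR called 0 of 7958 genes, with 219 at an unadjusted p under 0.05, and DESeq2 called 2 that rose and 2 that fell. Of 20 lists, camera called 7 with its preset correlation and 0 with an estimated one, and fry 0, with 1 at an unadjusted p under 0.05. Removal of IBS-D 2 ended the MHC class II call (adjusted p = 0.0815). That of the NF-kB list ended without IBS-D 2, normal 3 and IBS-D 1 (0.117, 0.0981 and 0.0618). Without normal 1, normal 3, IBS-D 1 and IBS-D 2 edgeR called 29, 9, 136 and 3 genes.

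In goblet-like cells, of which the libraries held 96, 99, 38 and 65, 10 of 11 inflammatory cytokine and NF-kB genes were higher (median log2 0.77, camera adjusted p = 1.71e-05, adjusted p = 0.429 with an estimated correlation). Adjusted over the list alone 3 chemokine genes rose and over all genes 0 did. They were Cxcl1 (5.69 to 78.9 CPM) and Cxcl2 (1.47 to 31.5), which attract neutrophils, and Ccl20 (9.47 to 37.7), which attracts lymphocytes and dendritic cells. The dissociation and heat shock list was also higher (17 of 20, median 0.77, adjusted p = 0.00352, adjusted p = 0.896 with an estimated correlation). Its call ended without normal 3 (0.241) and IBS-D 1 (0.713), and that of the NF-kB list was kept without each library (up to 0.0185). The mucus list had 10 of 13 genes lower (median -0.63, adjusted p = 0.0139, adjusted p = 0.782 with an estimated correlation), with 0 past either adjustment. The mucin glycosyltransferase Galnt3 stood at 79.0 to 45.7 CPM. The mucus list holds genes that set the goblet-like cluster apart, such as Muc2 and Zg16. The cell cycle list was higher in 8 of 8 genes (adjusted p = 0.429 with an estimated correlation). Of these genes 4 rose adjusted over the list alone and 0 over all genes. In the same cells Cd79a stood at 34.6 and 25.4 CPM in the normal and 59.6 and 15.6 CPM in the IBS-D libraries. Ribosomal protein genes held 2.63% and 1.72% against 6.86% and 1.83% of the UMIs. Their list was called higher (64 of 65, adjusted p = 1.01e-05, adjusted p = 0.896 with an estimated correlation) but lower without IBS-D 1 (0.00785), and it was not called without normal 3 (0.117). The nuclear oxidative phosphorylation list was higher (66 of 72, 1.36e-05 and 0.896), and not called without IBS-D 1 (0.752). Interferon response genes were lower (10 of 13, 0.0138 and 0.782), and not called without normal 3 (0.389). EdgeR called 1 gene of 8181, ENSRNOG00000065796, at 0 and 0 CPM in the normal and 83.1 and 83.9 CPM in the IBS-D libraries. It did not pass with cells thinned to 2000 UMIs (adjusted p = 0.124). In edgeR 522 genes had an unadjusted p under 0.05, and DESeq2 called 5 that rose and 2 that fell. Of 20 lists, camera called 7 with its preset correlation and 0 with an estimated one, and fry 0, with 3 at an unadjusted p under 0.05. Removal of normal 1 or IBS-D 1 ended the mucus call (adjusted p = 0.0650 and 0.0532). Without normal 1, normal 3, IBS-D 1 and IBS-D 2 edgeR called 38, 37, 32 and 412 genes.

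In plasma cell-like cells, 3 genes without a symbol fell and 0 rose in edgeR. ENSRNOG00000070816 fell from 697 and 1075 CPM to 0 in both IBS-D libraries (adjusted p = 2.80e-07). ENSRNOG00000070540, another of the 3, is among the leading genes by which the cluster of these cells stands apart and is therefore given no value. The plasma cell and IgA list had 11 of 12 genes lower (median -0.43, adjusted p = 0.00713, adjusted p = 0.668 with an estimated correlation), with the secretory regulator Xbp1 at 367 to 233 CPM. That list holds markers by which this cluster was named, such as Jchain and Xbp1, so it is not independent of the class. The unfolded protein response list had 16 of 18 lower (adjusted p = 0.0101, adjusted p = 0.668 with an estimated correlation). The 13 mitochondrially encoded genes, a sign of RNA quality, were all lower as well (median -0.31, 0.0101 and 0.668), a call that ended without normal 1 (0.797), IBS-D 1 (0.0705) and IBS-D 2 (0.0906). Cell cycle genes, for which the cluster of these cells has a cycling score of 1.546, were higher (15 of 19, 0.000105 and 0.668), and 4 of them rose adjusted over the list alone and 0 over all genes. The test covered 3479 genes, of which 310 had an unadjusted p under 0.05, and DESeq2 called 0 that rose and 3 that fell. Of 11 lists, camera called 4 with its preset correlation and 0 with an estimated one, and fry 0, with 0 at an unadjusted p under 0.05. Removal of normal 1 or IBS-D 1 ended the call of the plasma cell list (adjusted p = 0.0683 and 0.165), and removal of normal 3 or IBS-D 2 that of the unfolded protein response (0.0982 and 0.0906). Without normal 1, normal 3, IBS-D 1 and IBS-D 2 edgeR called 13, 55, 14 and 88 genes.

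In natural killer or cytotoxic innate lymphoid-like cells, edgeR called 0 of 3785 genes, with 207 at an unadjusted p under 0.05, and DESeq2 called 1 that rose and 2 that fell. Their mitochondrially encoded genes (median log2 -0.40, camera adjusted p = 6.44e-05, adjusted p = 0.722 with an estimated correlation) and nuclear oxidative phosphorylation genes (median -0.34, 0.000409 and 0.856) lay lower. The MHC class II presentation list was called higher (4 of 5, median 0.74, 0.0119 and 0.722), though not without normal 3 (0.995, reversed) or IBS-D 1 (0.343). Of 15 lists 3 were called with the preset and 0 with an estimated correlation, and 0 by fry, with 0 at an unadjusted p under 0.05. Removal of normal 1 and IBS-D 1 gave the oxidative phosphorylation list an adjusted p of 0.832 (reversed) and 0.0984. In these cells edgeR called 62, 74, 13 and 8 genes without normal 1, normal 3, IBS-D 1 and IBS-D 2.

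**Figure D3:**
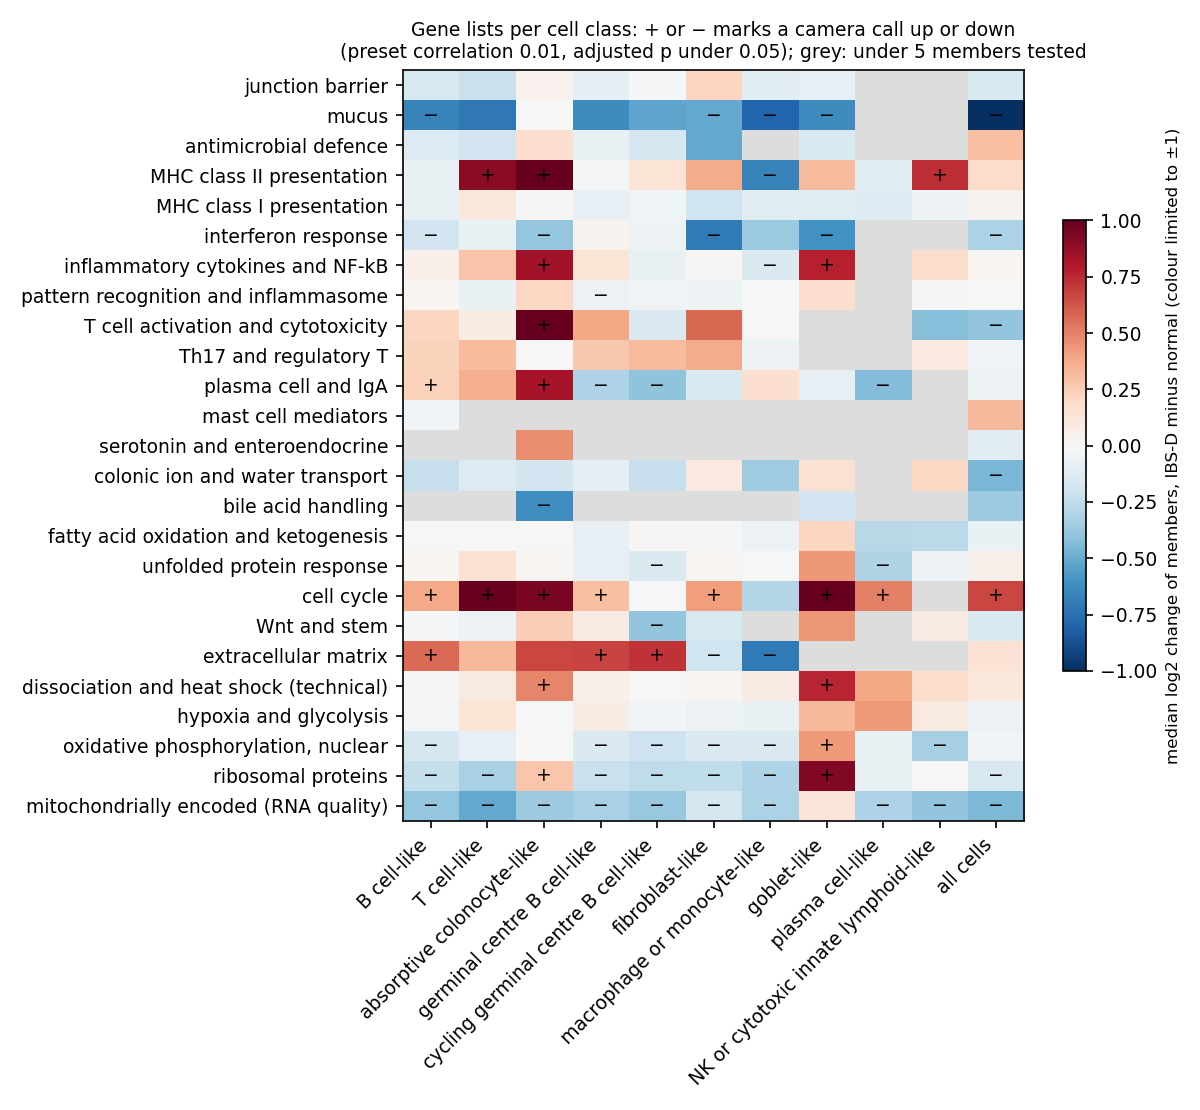
Median log2 change (IBS-D minus normal) of the members of each gene list in each cell class, with colour limited to 1 in either direction, a sign where camera with its preset correlation called the list and grey where fewer than 5 members were tested. Interferon response genes carry a minus sign in B cell-like, absorptive, fibroblast-like and goblet-like cells and over all cells, and 0 of all the calls were kept with an estimated correlation.

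Over all cells of a library, a view that mixes the makeup of the sample with changes within cells, ENSRNOG00000065796 rose from 0.824 ± 0.00735 to 92.9 ± 7.33 CPM (log2 6.75, SE 0.23, edgeR adjusted p = 0.0394). It was the only gene called of 17151, with 380 at an unadjusted p under 0.05, and DESeq2 called 22 that rose and 29 that fell. Among the genes that did not pass, means were 42.7 to 81.0 CPM for Arhgap6, 42.2 to 73.5 for the heat shock protein Hsph1, 28.3 to 50.7 for Clec3b, 70.4 to 131 for ST7 and 28.3 to 51.7 for the actin regulator Enah. In the other direction they were 47.3 to 11.98 CPM for Dbp, 65.8 to 15.6 for Per3, 165 to 42.3 for Sval1, 35.4 to 12.6 for Med18 and 31.6 to 16.6 for Calhm6. Of 25 lists camera called 7 with its preset correlation, with mucus genes lower (14 of 16, median log2 -1.0), interferon response genes lower (20 of 25, median -0.32) and ion and water transport genes lower (28 of 34, median -0.45). Among the others, T cell activation genes were lower (20 of 25, median -0.39) and cell cycle genes higher (25 of 25, median 0.67). Ribosomal protein and mitochondrially encoded genes were lower too (67 of 77 and 13 of 13). Each of these 7 lists had adjusted p = 0.976 with an estimated correlation. Fry called 0 lists, with 0 at an unadjusted p under 0.05. The list of mast cell mediators, tested over all cells, had an adjusted p of 0.247. Summed epithelial markers stood at 5188 and 11001 CPM in the normal and 2619.7 and 10533 CPM in the IBS-D libraries. Without normal 1 or normal 3 no gene passed (adjusted p = 0.955 and 1.000 for ENSRNOG00000065796, with log2 changes of 6.78 and 6.72), and without IBS-D 1 or IBS-D 2 edgeR called 6 and 5. Removal of IBS-D 1 ended the calls of T cell activation (0.276) and ion transport (0.451) and turned that of the cell cycle (0.0356). Removal of normal 3 ended the cell cycle call (0.146) and removal of normal 1 that of T cell activation (0.237). The ribosomal list was not called without normal 1 (0.602) or IBS-D 2 (0.654, reversed).

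Whether the model's effect differed between B cell-like and T cell-like cells was tested with an interaction term and the library as a block. The difference for Med18 was 0.18 on the log2 scale (SE 0.17), and 0 of 13158 genes passed in edgeR, with 560 at an unadjusted p under 0.05. Without the block 0 passed and 262 had an unadjusted p under 0.05. With normal 1, normal 3, IBS-D 1 and IBS-D 2 left out in turn, 1, 6, 37 and 396 genes passed.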

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

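The alternatives that took cluster 5 or cluster 7 alone, and the count of barcodes with eosinophil markers, were chosen after the data were seen, and the others before. Among single named genes, 1107 results under an alternative kept their direction and their side of the threshold, 59 no longer passed, 91 came to pass and 2 reversed. Among single called lists 197 were kept, 217 no longer passed and 12 reversed. All of the 197 came from leaving out a library, since the estimated correlation and fry called no list in any class. Among shares 187 were kept, 1 came to pass and 19 reversed. Of the counts of changed genes 86 stayed within a factor of 1.5 and 76 moved. Natural killer or cytotoxic innate lymphoid-like cells at resolution 0.5 were not run, since a library held too few of them. No paired analysis was possible because the groups share only 1 library number. Where a library is left out, the lone library of its group is assumed to vary like the others, and the cause of the changes below was not tested.

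The number of changed genes depended on the tool and the filter. DESeq2 called 29 genes in B cell-like, 17 in T cell-like, 146 in absorptive colonocyte-like and 11 in germinal centre B cell-like cells and 51 over all cells. Among these were all 6, 4, 7, 5 and 1 that edgeR called. With no count filter edgeR called 269, 25, 481, 85 and 2 in the same order. In absorptive colonocyte-like cells it called 3 with a mitochondrial share of at most 10%, 4 with no doublets removed, 21 with cells thinned to 2000 UMIs, 4 in cluster 5 alone and 2 in cluster 7 alone. The log2 change of Duoxa2 was 1.66 in cluster 5 alone and -0.41 in cluster 7 alone, and with no doublets removed that of Prim1 in germinal centre B cell-like cells was -0.16. Leaving out each library in turn gave 6 (without normal 3) to 48 (without IBS-D 2) changed genes in B cell-like cells, 3 (normal 1) to 64 (IBS-D 2) in T cell-like cells. It gave 1 (normal 1) to 25 (IBS-D 2) in absorptive colonocyte-like and 9 (normal 1) to 94 (IBS-D 2) in germinal centre B cell-like cells. It gave 0 (normal 1) to 6 (IBS-D 1) over all cells and 1 (normal 1) to 396 (IBS-D 2) genes whose effect differed between B cell-like and T cell-like cells.

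Camera with an estimated correlation called 0 lists in B cell-like, T cell-like, absorptive colonocyte-like and germinal centre B cell-like cells and over all cells, and fry called 0 in each. At an unadjusted p under 0.05 fry had 2, 0, 2, 1 and 0 lists. Leaving out each library in turn, camera with its preset correlation called 5 to 10 lists in B cell-like cells, 5 to 10 in T cell-like and 4 to 10 in germinal centre B cell-like cells. For lists that reversed, the adjusted p over the left-out libraries ran from 7.36e-12 to 0.208 for extracellular matrix in B cell-like, from 2.53e-14 to 0.920 in germinal centre B cell-like and from 1.24e-08 to 0.775 in macrophage or monocyte-like cells. For ribosomal proteins it ran from 4.23e-08 to 0.848 in absorptive colonocyte-like cells, from 4.48e-18 to 0.117 in goblet-like cells and from 7.63e-12 to 0.654 over all cells. For nuclear oxidative phosphorylation it ran from 5.07e-10 to 0.664 in germinal centre B cell-like, from 4.70e-06 to 0.484 in macrophage or monocyte-like and from 2.25e-08 to 0.832 in natural killer or cytotoxic innate lymphoid-like cells, in which MHC class II presentation ran from 0.00124 to 0.995. The cell cycle list over all cells ran from 1.61e-10 to 0.146.

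The direction of several shares turned with the setting. The log2 change of the absorptive colonocyte-like share was 0.0428 among epithelial cells and 0.12 with a mitochondrial share of at most 10%, and that of the tuft-like share was 0.38 among epithelial cells and 0.0438 with no doublets removed. At resolution 1.5, 1 share came to pass, that of cluster 29 (adjusted p = 0.0482), with the same log2 change. Leaving out each library, the log2 change ran from -1.23 to 0.28 for absorptive colonocyte-like and -0.34 to 1.49 for cycling germinal centre B cell-like cells. It ran from -2.69 to 1.57 for enteric glia-like, -0.47 to 0.90 for fibroblast-like, -0.49 to 1.55 for mesothelial-like and -0.63 to 0.60 for tuft-like cells. Without a turn in direction, it ran from 0.32 to 1.41 for germinal centre B cell-like, from 0.14 to 1.75 for mast cell-like and from 0.29 to 1.01 for natural killer or cytotoxic innate lymphoid-like cells, whose change was 0.0193 at resolution 1.5. The mesothelial-like share had 1.47 with no doublets removed. For unnamed clusters it ran from -0.83 to 0.84 (19), -0.15 to 1.11 (22), -0.55 to 0.58 (24), -1.52 to 1.76 (26) and -0.33 to 1.36 (28).

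Cell numbers differed between libraries, and depth per cell differed between the groups in most tested classes. Goblet-like cells numbered 96 and 99 in the normal and 38 and 65 in the IBS-D libraries, and plasma cell-like cells 48 and 54 and 35 and 41. The median UMIs per absorptive colonocyte-like cell were 10140 and 8408 in the normal and 6575.5 and 8062 in the IBS-D libraries. They were 5223 and 4991 against 3990 and 4300 in B cell-like and 5886 and 5471.5 against 3953 and 5089.5 in T cell-like cells. Both IBS-D medians lay below both normal medians in every tested class except goblet-like and plasma cell-like cells, where they overlapped. In the other classes depth per cell therefore cannot be told apart from the group.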

Other observations

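Of the tests below, those on the posterior Hox genes and on the correlation between clusters were chosen before their results were seen, and the others only after. Clock genes of fibroblast-like cells lay apart in both directions. Dbp, which passed in edgeR, and Per3 (100.2 to 29.1 CPM) were lower in IBS-D. Their opponents in the clock cycle were higher: Bmal1, which switches the cycle on, from 16.7 to 94.3 CPM (log2 2.41), its partner Npas2 from 32.7 to 104 and the repressor Nfil3 from 83.6 to 175, none of these 4 past the adjusted threshold. Absorptive colonocyte-like cells had Bmal1 at 28.3 ± 27.0 to 151 ± 53.5 CPM (SD, n = 2). The median change of the Dbp group minus that of the Bmal1 group was -3.18 on the log2 scale in absorptive colonocyte-like, -3.04 in goblet-like and -2.84 in fibroblast-like cells. It was -0.47 in B cell-like, -0.44 in germinal centre B cell-like, -0.42 in macrophage or monocyte-like, -0.32 in T cell-like and -0.19 in cycling germinal centre B cell-like cells. Whether these classes differ in it was not tested.

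Genes known to escape silencing on the inactive X chromosome lay higher in IBS-D over all cells, 4 of 4 tested, with a median log2 change of 0.56. The histone demethylases Kdm6a and Kdm5c stood at 174 to 304 and 51.1 to 72.2 CPM, the translation factor Eif2s3 at 83.7 to 139.5 and the RNA helicase Ddx3x at 139 to 196, none of them past the adjusted threshold in edgeR. Within single classes their median log2 change ran from 0.23 in goblet-like to 0.74 in natural killer or cytotoxic innate lymphoid-like cells. Of the 4 genes 3 were higher in goblet-like cells and all 4 in each other tested class, with none past the adjusted threshold. Barcodes with UMIs of at least 2 of 6 eosinophil markers numbered 5 and 6 in the normal and 11 and 19 in the IBS-D libraries, a count made after the data were seen. With these numbers in place of cluster 29, the log2 change of its share was 1.22 (edgeR adjusted p = 0.693), against 2.60.

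Clock genes lay apart between the groups in absorptive colonocyte-like, goblet-like and fibroblast-like cells. Collection at different times of day may account for this. The difference between the Dbp and Bmal1 groups lay below -0.5 in 3 of 8 classes. The classes above that bound met the number set against this cause, a rule that did not count their spread. B cell-like (-0.47, spread 0.13) and T cell-like cells (-0.32, spread 0.22) lay within their spread of the bound. So did germinal centre B cell-like (-0.44, spread 0.28) and macrophage or monocyte-like cells (-0.42, spread 0.49). The values therefore do not decide. Stress during dissociation stays open too: of the 3 classes with a clock shift, 1, the fibroblast-like cells, had a median of the dissociation list under 0.25 in size (0.02), and the others 0.49 and 0.77. A shift of the clock by the model itself is a hypothesis that the design cannot part from collection time, because no collection times are given and the permutation p of the shift is 0.3333, the smallest that 2 against 2 libraries allow.

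ENSRNOG00000065796 was near 0 in the normal libraries and had UMIs in both IBS-D libraries in each of 10 compared classes. It passed in 7 of them, not in macrophage or monocyte-like (adjusted p = 0.136) or natural killer or cytotoxic innate lymphoid-like cells (0.117), and was not tested in plasma cell-like cells, with 7 and 11 UMIs. It was the 1 feature called with a log2 change of at least 3 in size in at least 5 classes. ENSRNOG00000037911 was also called, and higher, in B cell-like (log2 2.85), T cell-like (2.79), absorptive colonocyte-like (6.48), germinal centre B cell-like (3.23) and cycling cells (2.68). ENSRNOG00000068013 rose in B cell-like (2.22 to 127 CPM) and germinal centre B cell-like cells (8.01 to 95.2 CPM). In the latter it did not pass with no doublets removed. The rule was narrowed after a wider set of 4 features, called so in at least 2 classes, had been seen, whose median ratio of highest to lowest class was 14.1. Free RNA shed by 1 of the 10 compared classes is not decided by the ratio of ENSRNOG00000065796, 3.59 (32.8 to 117.7 CPM). That ratio lay between the bounds set, at least 5 for free RNA and under 3 against it. The median of 14.1 of the wider set met the first bound. It rests on the ratios of ENSRNOG00000068013 (54.3) and Trio (23.5), while that of ENSRNOG00000037911 was 4.73. A gene expressed in few classes has a high ratio as well, so meeting this bound decides nothing. Choosing a feature called in many classes also favours a low ratio. For markers of single classes that ratio was 37.2 (Cd79a) to 3656 (Zg16), a comparison added after the wider set had been seen. Free RNA of cells outside these classes was not tested. A litter or strain variant stays open and cannot be told apart from the model without the animals' origins. Both libraries of a group lay on one side in 10 of 10 classes, which follows largely from how the feature was chosen and decides nothing. Whether the normal rats were male and the model rats female is not decided either. Over all cells the Y-linked genes summed to 0.196 and 0.173 CPM in the normal and 0.0847 and 0.163 CPM in the IBS-D libraries. The normal sums lay under the bound set against this cause. The genes that escape X silencing lay higher in IBS-D, the direction set for it. No library known to be male shows whether the Y-linked features count reads, so the low sums decide nothing.

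Absorptive colonocyte-like cells of the 2 groups lay mostly in different clusters, with 24.2 ± 5.84% in cluster 5 in normal and 76.7 ± 13.03% in IBS-D libraries (SD, n = 2, exact permutation p = 0.3333). Clusters set apart by the group difference alone cannot be told apart from a state present in both groups. The ratio of cluster 5 to cluster 7 correlated across 5401 genes between normal and IBS-D libraries (Pearson r = 0.614, Spearman's rho = 0.508, across genes, which are not independent replicates). But cells of both groups were placed in these clusters by the same expression, which can give such a correlation by itself, so the bound of 0.6 set for it beforehand decides nothing. For stress during dissociation, the list's median in B cell-like, T cell-like and fibroblast-like cells was at most 0.0906. This lay short of the 0.3 set for this cause and under the 0.1 set against it. That rule did not count the spread over the list's members. With the spread counted, too few of these classes stayed under 0.1 to decide. These cells may also respond less than the epithelium, so stress stays open. Sampling of different stretches of the colon might also contribute: the median change of 5 posterior Hox genes in fibroblast-like cells was -0.42 with a spread of 0.20, within that spread of the bound of 0.58.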
